A study of Homo sapiens with 6 samples.

How the data were processed

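RNA was sequenced from SKM-1 cells treated for 48 h with celastrol (3 libraries) or DMSO (3 libraries); groups and replicate numbers come from the sample titles. Total RNA was extracted with a phenol reagent and made into libraries with Illumina protocols, per the labels' protocols. Whether polyadenylated RNA was selected, and whether the kit kept strand, is not given in the sources used here, so reads of a gene and of an overlapping antisense gene may not be told apart.

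The deposited file holds FPKM, fragments per kilobase of gene scaled by a library total, for each gene and library, with gene length, position and biotype. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5.0-p3 were used with GRCh38 (hg38); their settings are not given in the sources used here. All 58735 gene identifiers and positions in the file matched GENCODE release 29 for GRCh38. The deposited FPKM multiplied by gene length was a whole multiple of 1 step per library for 100% of values above 0 (within 0.001 of a read), so reads could be recovered: 15231742, 15749792 and 16231066 for celastrol replicates 1 to 3 and 14953738, 13549187 and 15410904 for DMSO replicates 1 to 3. The total that the authors divided by was 1.04, 1.05 and 1.04 times these listed reads for celastrol replicates 1 to 3. For DMSO replicates 1 to 3 it was 0.963, 0.994 and 0.965 times. How it was set is not given in the sources used here. This ratio differs by treatment, so the deposited values lower celastrol relative to DMSO when compared with scaling to listed reads. Genes that share near-identical copies (HSPA1A and HSPA1B, the alpha globins, the AKR1C genes, ferritins, ribosomal proteins and mitochondrial genes with nuclear copies) have uncertain values, since reads can be divided between copies. All 6 value columns of the file belong to these samples.

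Tests used limma 3.58.1 in R 4.3.3. Values were log2(FPKM + 0.1), so fold changes of low genes are understated, and genes needed a mean FPKM of at least 1 over the 6 libraries. The model was limma-trend with treatment as its single term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05; adjusted p-values of genes in the text come from it. Means with SD and fold changes between means are of FPKM itself, and log2 fold changes with SE are from limma. A total of 36 gene lists, the tests and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested genes (33 of 36) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data; under the latter none of the 19 calls held. Members were counted from the adjustment over all genes tested and from an adjustment over the list alone. Some lists share genes, such as CHAC1, SLC7A11 and SLC3A2.

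Genes are named by a rule: the 10 largest log2 fold changes in each direction among called protein-coding genes whose groups do not overlap and whose higher mean is at least 5 FPKM; up to 4 called members by size of each list that passed camera or had at least 5 called members; up to 2 members of highest mean FPKM of the other lists; and HMOX1, HSPA1A, HSPA1B, DNAJB1, DDIT3, CDKN1A, MYC, MCL1, BCL2, HSP90AA1, HSP90AB1, CDC37, GCLM, NFKBIA, GAPDH and ACTB whatever their result. Some genes that the rule takes, and 1 of the 36 lists, are not reported here. Genes outside the rule are marked as chosen after their values were seen.

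Replicates were compared before they were averaged. A chi-square test of recovered reads over genes with at least 20 reads in a pair gave 4.01 to 13.4 per gene for pairs within a treatment, so no library repeated another, and 49.3 to 77.7 for pairs across treatments. Pearson correlations of the log2 values across genes, which are not independent replicates, were 0.959 to 0.967 within and 0.928 to 0.943 across treatments. The first principal component held 45.5% of the variance and separated the treatments.

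The steps were tested on simulated counts drawn from the means and depths of these libraries, with 200 genes changed. Every gene had the same dispersion, 0.0037, taken from well-covered genes. Noise that differs between genes, or that 1 library shares over many genes, was left out. The counts below are therefore not error rates for the real data. In the simulated comparison of celastrol against DMSO over 12681 genes, limma-trend called 58 of 96 genes changed by 1.41-fold, 82 of 95 changed by 2-fold and 9 of 12490 unchanged genes. Camera called the list that was moved and 0 of 30 unmoved lists. The simulated genes were drawn independently, so their lists held no correlation between genes. Estimated correlations of the real lists reached 0.676, for the mitochondrially encoded mRNAs. The simulation therefore does not measure how often camera calls unmoved lists of correlated genes.

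The alternatives fixed before the data were seen were pseudocounts of 1 and 0.01, no filter on low values, a minimum mean FPKM of 5, median-of-ratios scaling, TPM, quantile normalization, limma-trend with robust variance, limma without a trend, the replicate number as a block, each library left out in turn, protein-coding genes alone, limma-voom on the recovered reads, and camera with an estimated correlation. Added after seeing the data were scaling to listed reads, scaling to nuclear reads, and removal of loess trends on transcript GC and gene length from the log2 fold changes.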

Results

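Gene expression was measured by RNA sequencing in SKM-1 cells, a human acute myeloid leukaemia cell line, after 48 h with celastrol or with DMSO. Celastrol is a triterpenoid from the root of the thunder god vine, Tripterygium wilfordii, and DMSO is the solvent control. Each treatment had 3 libraries. The deposited table lists FPKM for 58735 genes of GRCh38, and the reads behind those values came to between 15231742 and 16231066 per celastrol library and between 13549187 and 15410904 per DMSO library. The dose of celastrol is not given in the sources used here. Nothing says that the 3 libraries of a treatment came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical.

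The design asks which transcripts differ between SKM-1 cells treated with celastrol and with its solvent. All 13 mitochondrially encoded mRNAs were lower with celastrol, with a median log2 fold change of -1.71 (adjusted p = 0.318 with an estimated correlation). Under quantile normalization 11 of 13 were lower and the median was -0.86. Genes of the integrated stress response, the program that the transcription factor ATF4 drives under amino acid shortage or protein-folding stress, also fell, with 23 of 25 tested members lower and a median of -1.26 (adjusted p = 0.293 with an estimated correlation). Erythroid genes fell in 11 of 14 tested members, with a median of -1.32 (adjusted p = 0.114 with an estimated correlation). Targets of NRF2, the main transcription factor of the antioxidant response, rose in 13 of 22 tested members, and glycolysis genes rose in 11 of 22 (adjusted p = 0.483 and 0.445 with an estimated correlation). The gene with the largest increase by the naming rule was GADD45B, a stress-inducible regulator of growth arrest, at 11.5 ± 0.516 FPKM with celastrol and 1.34 ± 0.476 with DMSO (SD, n = 3 each).

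**Figure D1:**
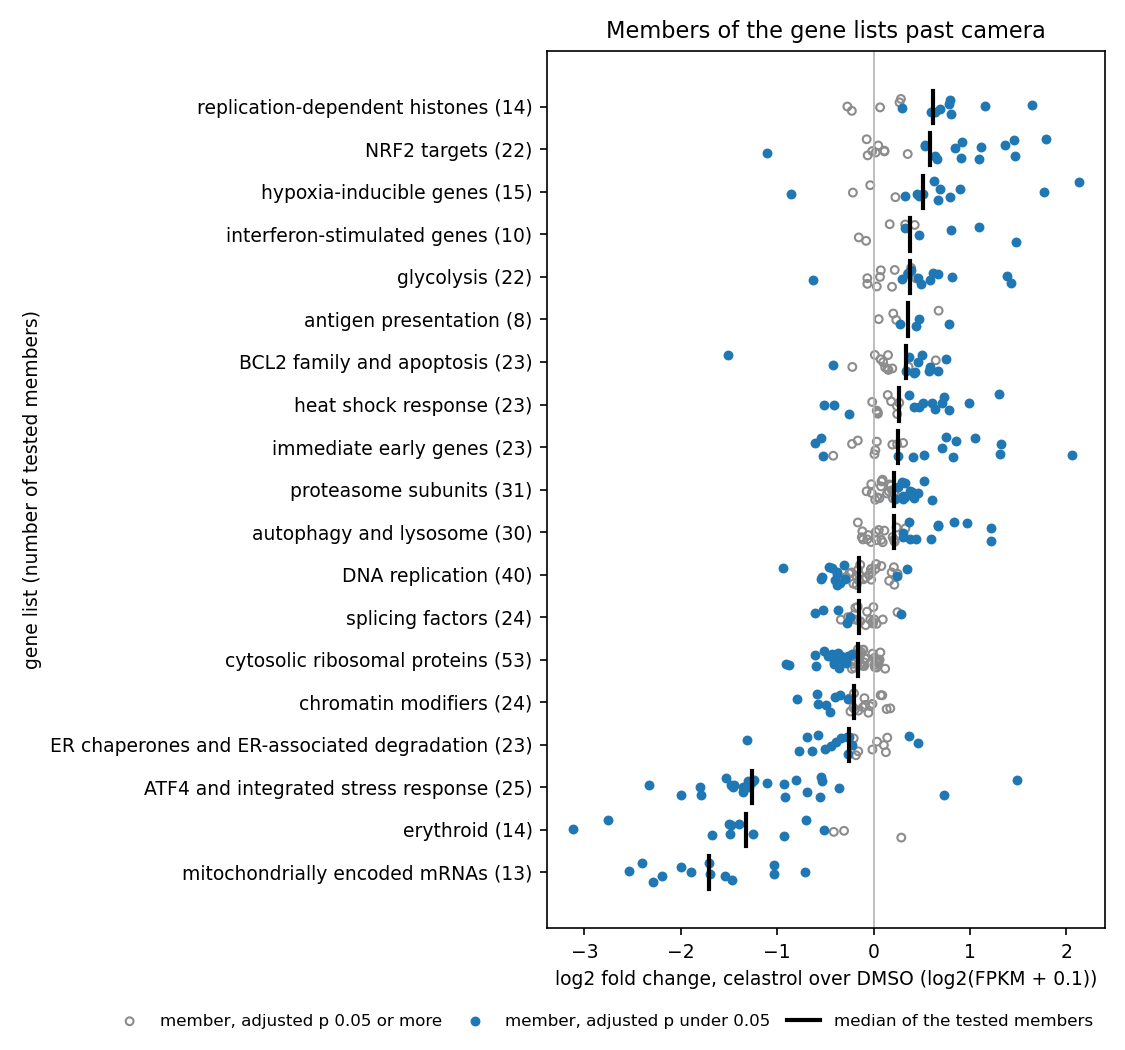
Log2 fold change of each tested member of the 19 gene lists that passed limma's camera, celastrol over DMSO on the log2(FPKM + 0.1) scale. Filled points are members with an adjusted p under 0.05, open points are the others, and black bars are list medians, which run from -1.71 for the mitochondrially encoded mRNAs to 0.62 for the replication-dependent histones; the medians of the DNA replication, splicing, chromatin and ribosomal protein lists turn above 0 when values are rescaled to TPM.

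Of 12685 genes tested with limma-trend at a Benjamini-Hochberg adjusted p under 0.05, 1947 were higher and 1797 were lower with celastrol. Among these, 184 were at least 2-fold higher and 269 at least 2-fold lower. The celastrol and DMSO values did not overlap for 6005 genes, 47.3% of those tested, where chance gives 10%. Higher genes made up 52% of the calls as deposited, 86.6% after rescaling to TPM (5266 higher, 813 lower) and 70% when scaled to listed reads (3024 higher, 1295 lower), because these scalings moved the median log2 fold change of all tested genes from 0.02 to 0.26 and 0.12. Small changes are therefore relative to that median. None of the 19 list calls held with a correlation estimated from the data. The erythroid and splicing lists had estimated correlations of -0.0049 and -0.0062, below the preset 0.01, and still lost their calls. A higher correlation therefore does not account for those losses. How often this form of camera can call a moved list with 6 libraries was not measured. With the preset correlation, camera also called 5 to 15 lists when the 6 libraries were divided so that the treatments mixed. Each such division mixes the treatments unevenly, so part of their difference remains and these need not be false calls. Single libraries moved the counts by more than 1.5 times: without celastrol replicate 2 there were 1119 higher and 1137 lower genes, without celastrol replicate 3 there were 1211 higher, and without DMSO replicate 3 there were 1140 higher and 1003 lower.

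By the naming rule, which asks for a mean of at least 5 FPKM in the higher group, the protein-coding genes with the largest increases after GADD45B (chromosome 19, 2476122 to 2478259; log2 fold change 3.07, SE 0.22, adjusted p = 0.000166) were TEX19, ACP5, TMEM158, SLC20A1, CLEC2B, AIF1, IFI16, PHLDA2 and RHOB, with log2 fold changes from 2.52 for TEX19 to 1.84 for RHOB. The abundant ones among them were TMEM158 (chromosome 3, 45224466 to 45226278), which averaged 156 FPKM with celastrol and 30.6 with DMSO, and the phosphate transporter SLC20A1 (chromosome 2, 112645857 to 112663827), which was 5.10-fold higher at 153 ± 19.4 FPKM (SD, n = 3). ACP5, tartrate-resistant acid phosphatase, was 6.41-fold higher on average, and its celastrol libraries lay at 2.82, 5.32 and 9.86 FPKM. By the same rule the largest decreases were in MT-CO2, PKLR, MT-ND2, CHAC1, ASS1, MT-CO3, KIT, MT-CYB, KEL and DES. PKLR, the pyruvate kinase of liver and red cells (chromosome 1, 155289293 to 155301438), was 5.92-fold lower with celastrol, at 1.33 ± 0.373 FPKM against 7.88 ± 0.407. KIT, the stem cell factor receptor (chromosome 4, 54657918 to 54740715), was 5.01-fold lower, at 1.05 ± 0.0948 against 5.28 ± 0.180 FPKM. ASS1, argininosuccinate synthase, was 5.29-fold lower, and the intermediate filament gene DES was 4.37-fold lower. All 20 of these genes kept their call without each library in turn.

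**Figure D2:**
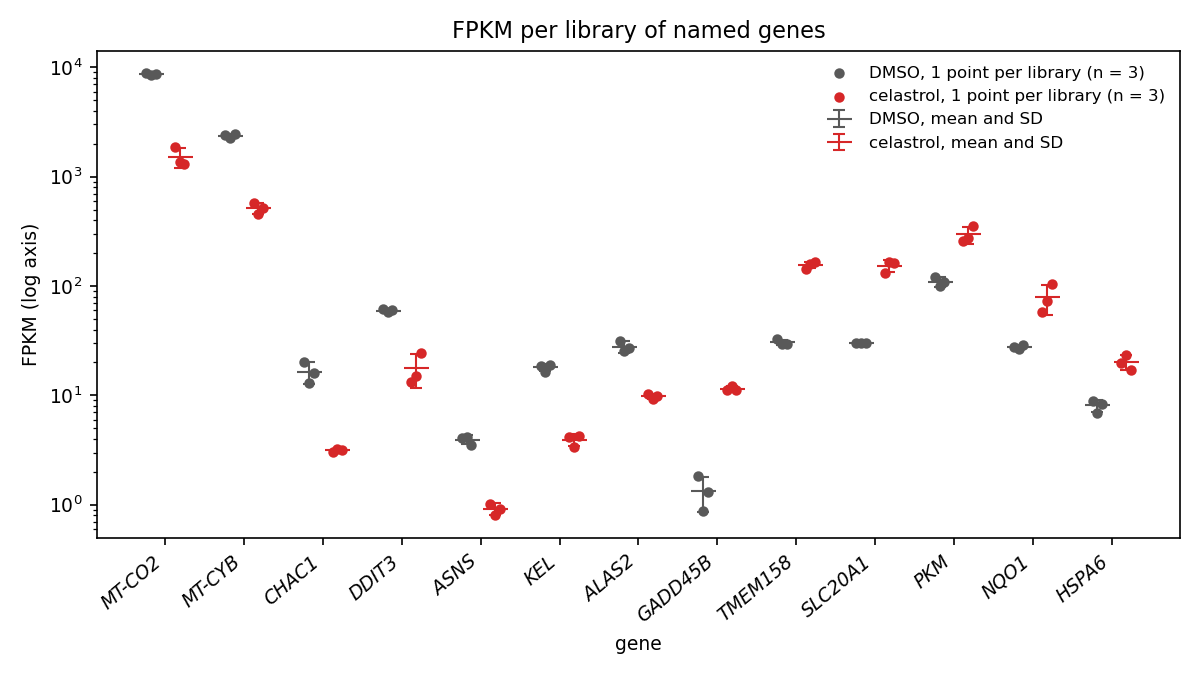
FPKM on a log axis of 13 named genes in each library, with the mean and SD of 3 libraries per treatment (grey, DMSO; red, celastrol). No celastrol value overlaps a DMSO value for any of them; MT-CO2 lies at 1519 against 8716 FPKM on average and GADD45B at 11.5 against 1.34.

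Mitochondrially encoded mRNAs, which specify subunits of the respiratory chain and ATP synthase, were lower in 13 of 13 members, also 13 when adjusted over the list alone. MT-CO2 (mitochondrial chromosome, 7586 to 8269) fell from 8716 ± 170 to 1519 ± 313 FPKM, a 5.74-fold decrease (adjusted p = 7.26e-05). MT-CO3 fell from 10690 ± 118 to 2214 ± 373 FPKM, MT-ND2 from 3046 ± 171 to 584 ± 112, and MT-CYB from 2371 ± 83.8 to 518 ± 60.2 (SD, n = 3). Under quantile normalization 11 of the 13 were lower and the median was -0.86. The decrease was unequal along the genome, from a log2 fold change of -2.54 for MT-CO2 to -0.71 for MT-ATP8. MT-ATP8 overlaps MT-ATP6, which lay at -2.00, so reads of these genes can be exchanged. The list passed camera (adjusted p = 1.96e-14), and its adjusted p was 0.318 with an estimated correlation. Reads on all mitochondrial genes made up 1.54 ± 0.271% of each library with celastrol and 5.52 ± 0.113% with DMSO (SD, n = 3; two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). The 35 tested nuclear genes of oxidative phosphorylation moved both ways, with 4 higher and 6 lower, also when adjusted over the list alone (camera adjusted p = 0.231). Among them ATP5F1A, a subunit of ATP synthase, was 1.68-fold lower and UQCRC2, of complex III, 1.39-fold lower, while NDUFB3, of complex I, and SDHC, of complex II, rose by log2 fold changes of 0.72 and 0.50. NDUFB3 lost its call with no filter on low values (adjusted p = 0.0551). Reads from MT genes and their nuclear copies can be exchanged, since the sequences are nearly alike.

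**Figure D3:**
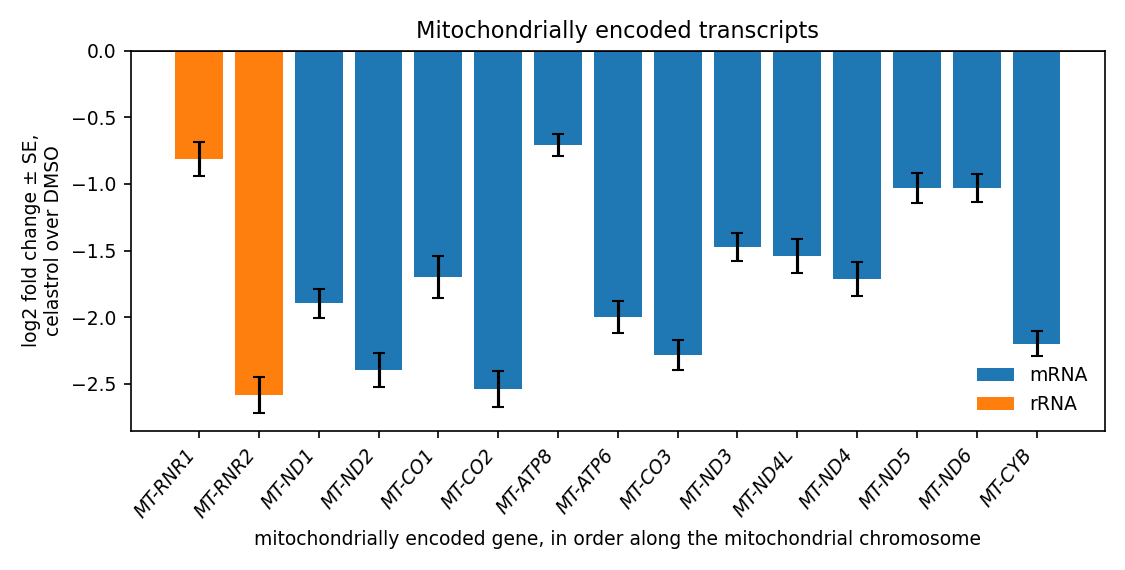
Log2 fold change with its standard error (celastrol over DMSO, n = 3 each) of the 13 mRNAs and 2 rRNAs of the mitochondrial genome, in order along the chromosome. All 15 lie below 0, from -2.58 for MT-RNR2 to -0.71 for MT-ATP8.

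The ATF4 and integrated stress response list had 23 members lower and 2 higher of 25 tested, also when adjusted over the list alone. CHAC1, which degrades glutathione (chromosome 15, 40952962 to 40956519), fell from 16.5 ± 3.69 to 3.16 ± 0.101 FPKM (log2 fold change -2.33, SE 0.15, adjusted p = 0.000125). Asparagine synthetase, ASNS, fell from 3.93 ± 0.366 to 0.914 ± 0.113 FPKM, the mTORC1 inhibitor DDIT4 from 246 ± 45.5 to 70.0 ± 6.49, and DDIT3, which encodes CHOP, from 59.5 ± 1.93 to 17.7 ± 6.01 (SD, n = 3). The members that rose were NUPR1 and SLC3A2, named here after their values were seen. Camera called the list lower (adjusted p = 1.35e-15; adjusted p = 0.293 with an estimated correlation). Chaperones and degradation factors of the endoplasmic reticulum followed, with 13 of 23 lower and 2 higher, or 14 and 2 when adjusted over the list alone. HERPUD1 was 2.50-fold lower, the main chaperone HSPA5 was 1.71-fold lower, CALR 1.62-fold lower and XBP1 1.55-fold lower. That list had a median of -0.25 (camera adjusted p = 0.000525; adjusted p = 0.396 with an estimated correlation).

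Markers of the erythroid lineage were expressed in this culture and fell with celastrol in 11 of 14 tested members, or 12 when adjusted over the list alone (camera adjusted p = 6.15e-08; adjusted p = 0.114 with an estimated correlation). AHSP, the stabiliser of alpha globin, lay at 0.399 ± 0.168 FPKM against 4.09 ± 0.564 (SD, n = 3), with as few as 2 reads in a library. The anion exchanger SLC4A1 was 8.57-fold lower, GYPB 3.41-fold lower and ALAS2, the first enzyme of haem synthesis in red cells, 2.85-fold lower. KEL, the Kell blood group protein, fell from 18.0 ± 1.48 to 3.92 ± 0.482 FPKM. The fall was not shared by every erythroid gene. RHAG averaged 290 ± 5.96 FPKM with celastrol and 261 ± 12.4 with DMSO. TAL1 lay at 26.0 ± 0.318 against 24.4 ± 0.756, and HBG2 at 30.7 ± 5.17 against 25.5 ± 6.46. These 3 were chosen after their values were seen. The other lineage lists were mostly under the minimum mean of 1 FPKM: tested were 11 of 27 stem and progenitor genes, 5 of 12 megakaryocyte, 6 of 30 monocyte and macrophage, 4 of 25 granulocyte, 3 of 18 lymphoid and 6 of 17 epithelial and stromal genes. Of the stem and progenitor list, 5 of 11 tested members were lower and 1 was higher, or 5 and 2 when adjusted over the list alone, and the list missed the threshold (camera adjusted p = 0.185). Its lower members included KIT, LMO2 at 1.77-fold and the transcription factor MYB at a log2 fold change of -0.59, while GATA2 rose by a log2 fold change of 0.53. Of 5 tested megakaryocyte genes 3 were lower, also when adjusted over the list alone, among them NFE2 and TUBB1 at log2 fold changes of -0.59 and -0.73. The megakaryocyte list missed the threshold (camera adjusted p = 0.0690) and passed it under TPM (0.0124), with protein-coding genes alone (0.0309), with limma-voom (0.0297), when scaled to listed (0.0305) or nuclear reads (0.0469), and without celastrol replicate 1 (0.0283). The range over the alternatives was 0.0124 to 0.483, and its upper end is the adjusted p = 0.483 with an estimated correlation. Of 6 tested monocyte and macrophage genes, 2 were higher and 2 lower, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.600); FCGR2A rose by 0.45, a call lost without celastrol replicate 2 or DMSO replicate 3 (highest adjusted p = 0.0557), and lysozyme, LYZ, was 2.15-fold lower. The granulocyte list had 4 tested genes, too few for camera, with SRGN higher by 1.09 and the neutrophil granule protein AZU1 1.74-fold lower, and 1 higher and 2 lower when adjusted over the list alone. Of 3 tested lymphoid genes, CD3D and NKG7 were higher, also when adjusted over the list alone, and CD3D lost its call without DMSO replicate 3 (adjusted p = 0.0597). Of 6 tested epithelial and stromal genes 2 were higher and 2 lower, or 2 and 3 when adjusted over the list alone (camera adjusted p = 0.725), with KRT18 higher by 0.39 and KRT19 lower at -0.28 on the log2 scale, a call that among the left-out libraries held only without DMSO replicate 2 (highest adjusted p = 0.133) and was lost under TPM (0.680), when scaled to listed reads (0.0912) and with no filter on low values (0.109).

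NRF2 targets rose in 13 of 22 tested members and fell in 1, or 14 and 1 when adjusted over the list alone (median 0.59; camera adjusted p = 0.000300; adjusted p = 0.483 with an estimated correlation). NQO1, a quinone reductase, went from 27.7 ± 1.23 to 78.7 ± 24.3 FPKM. Celastrol replicate 3 was the highest library for this gene and several others: replicates 1 to 3 had 58.0, 72.6 and 105 FPKM of NQO1, 16.8, 20.9 and 37.8 of AKR1C2, and 4776, 5543 and 7734 of the ferritin gene FTL. The aldo-keto reductases AKR1C2, AKR1C1 and AKR1C3 rose by log2 fold changes of 1.79, 1.47 and 1.36; these copies are nearly identical, so reads can be split between them. GCLM, which limits glutathione synthesis, rose by 0.54 (adjusted p = 0.0370), a call lost without celastrol replicate 2 or 3 or DMSO replicate 1 or 3 (lowest adjusted p of these 4 = 0.0726) and with no filter on low values (0.115). The cystine importer SLC7A11, also a target of ATF4, was the member that fell, by 2.16-fold. HMOX1, the haem oxygenase that NRF2 drives in many cells, lay at 0 to 0.198 FPKM, with 0 to 8 reads per library, and was not tested. The ferroptosis and iron list went both ways, with 3 higher and 3 lower of 18, also when adjusted over the list alone (camera adjusted p = 0.299). Its ferritin genes rose, with FTL at 6018 ± 1535 against 2755 ± 30.4 FPKM and FTH1 at 835 ± 217 against 436 ± 23.2, values that ferritin pseudogenes can share reads with. FTL lost its call with no filter on low values (adjusted p = 0.110). Of 9 metallothionein and metal response genes 2 were tested, and both, SLC30A1 and MT2A, were higher, by 0.83 and 0.66, also when adjusted over the list alone.

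Heat shock genes were higher in 11 and lower in 3 of 23 tested members, or 13 and 3 when adjusted over the list alone (median 0.27; camera adjusted p = 0.00215; adjusted p = 0.370 with an estimated correlation). HSPA6, a strictly inducible HSP70 gene, went from 8.09 ± 1.02 to 20.1 ± 3.20 FPKM, HSPB1 from 164 ± 20.1 to 271 ± 13.9, and HSPA1L and DNAJB4 rose by 0.99 and 0.79. HSPA1A and HSPA1B, nearly identical copies, rose by 0.64 and 0.61, and HSPA1B narrowly lost its call without celastrol replicate 2. The HSP90 genes parted: HSP90AA1 rose by 0.37 (adjusted p = 0.0136), and HSP90AB1 was lower at -0.41 (adjusted p = 0.00418), a direction that quantile normalization turned to 0.19. DNAJB1 was at -0.01 (adjusted p = 0.905) and turned above 0 under TPM, when scaled to listed or to nuclear reads, and without DMSO replicate 3 (0.05). Under TPM DNAJB1 passed as higher (adjusted p = 0.0383). With no filter on low values HSPA1A, HSPA1B, HSP90AA1 and HSP90AB1 lost their calls (adjusted p = 0.0519, 0.0550, 0.0702 and 0.128), and HSP90AB1 also under TPM (0.0504). The HSP90 cochaperone CDC37, at 0.25, did not pass (adjusted p = 0.0928). CDC37 passed under TPM (0.00292), quantile normalization (0.0412) and limma-voom (0.0366), when scaled to listed (0.0223) or nuclear reads (0.0447), and without DMSO replicate 1 (0.0236). Proteasome subunits were higher in 13 of 31 members and lower in none, or 14 and none when adjusted over the list alone, with PSMB6 higher by 0.60 the assembly factor POMP by 0.52, PSMD12 by 0.46 and ADRM1 by 0.42 (median 0.22; camera adjusted p = 0.000274; adjusted p = 0.480 with an estimated correlation). PSMD12 lost its call without celastrol replicate 3 (adjusted p = 0.0522), and ADRM1 kept it only without DMSO replicate 1 (highest adjusted p = 0.108). With no filter on low values POMP and ADRM1 lost theirs (0.0630 and 0.111). Autophagy and lysosome genes were higher in 12 of 30 and lower in none, or 13 and none when adjusted over the list alone (median 0.22; camera adjusted p = 0.00283; adjusted p = 0.459 with an estimated correlation). The lysosomal calcium channel MCOLN1 rose by 1.22 and the cathepsins CTSL and CTSB by 1.22 and 0.84. Celastrol replicate 3 was again the highest library for both cathepsins, with 66.6, 87.9 and 136 FPKM of CTSL and 88.9, 103 and 133 of CTSB in replicates 1 to 3.

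Glycolysis genes were higher in 11 and lower in 1 of 22 members, or 14 and 1 when adjusted over the list alone (median 0.37; camera adjusted p = 0.000131; adjusted p = 0.445 with an estimated correlation). Pyruvate kinase PKM went from 110 ± 11.1 to 297 ± 52.1 FPKM, against the fall of its erythroid paralog PKLR. The lactate exporter SLC16A3 rose by 1.39, the glucose transporter SLC2A3 by 0.82 and PGAM1 by 0.67. GAPDH, at 427 ± 23.9 against 447 ± 21.8 FPKM, did not pass (log2 fold change -0.07, adjusted p = 0.530), and its sign turned under TPM, quantile normalization and scaling to listed reads. Under TPM GAPDH passed as higher (adjusted p = 0.0330). ACTB, at 818 ± 21.8 against 715 ± 51.1 FPKM, also missed the threshold (adjusted p = 0.0837). ACTB passed under TPM (0.00113) and quantile normalization (0.000510), when scaled to listed (0.0113) or nuclear reads (0.0285), and without DMSO replicate 1 (0.0436). Hypoxia-inducible genes were higher in 11 and lower in 1 of 15, also when adjusted over the list alone (median 0.51; camera adjusted p = 0.000761; adjusted p = 0.318 with an estimated correlation). ANGPTL4, EGLN3 and ANKRD37 rose by 2.13, 1.77 and 0.90, ANKRD37 losing its call without celastrol replicate 2 (adjusted p = 0.0552), and VEGFA was 1.81-fold lower. Cholesterol synthesis genes moved both ways, with 7 higher and 4 lower of 25, also when adjusted over the list alone (camera adjusted p = 0.442); SC5D and INSIG1 rose by 0.78 and 0.53, and the regulator SREBF2 was 1.44-fold lower. SREBF2 lost its call without DMSO replicate 3 (adjusted p = 0.0524) and under TPM (0.0736). Fatty acid genes did as well, with 3 higher and 5 lower of 18, also when adjusted over the list alone (camera adjusted p = 0.299), and ACACA and FASN, which make fatty acids, FADS1 and ACSL1 were 1.81-fold, 1.63-fold, 1.65-fold and 1.59-fold lower.

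DNA replication genes were lower in 12 and higher in 2 of 40 members, also when adjusted over the list alone, with the licensing factor CDT1 1.91-fold lower, TYMS 1.46-fold, ORC1 1.44-fold and LIG1 1.37-fold lower. Camera called that list lower (median -0.15; adjusted p = 0.00755; adjusted p = 0.538 with an estimated correlation), while under TPM its median was 0.09 and the call was lost (adjusted p = 0.140), as were those of ORC1 (0.0689) and LIG1 (0.106). Replication-dependent histones were higher in 9 of 14 and lower in none, or 11 and none when adjusted over the list alone, with HIST1H4C, HIST1H2BC, HIST1H2BD and HIST1H3B higher by 1.65, 1.15, 0.80 and 0.79 (median 0.62; camera adjusted p = 0.000225; adjusted p = 0.344 with an estimated correlation). HIST1H4C rested on only 3 to 23 reads per library, and HIST1H3B lost its call without celastrol replicate 1 or 2 (highest adjusted p = 0.0728). Since it is not given whether polyadenylated RNA was selected, how fully histone mRNAs were captured is not known. Their change may not hold for all transcripts of these genes. Mitosis genes missed the threshold, with 7 higher and 2 lower of 32, also when adjusted over the list alone (camera adjusted p = 0.160). They passed it without celastrol replicate 3 (0.0455) and without DMSO replicate 2 (0.0223), within a range of 0.0223 to 0.690, with adjusted p = 0.690 with an estimated correlation. HMMR, BUB1 and ANLN rose by 0.59, 0.45 and 0.39, and the kinase AURKB was 1.47-fold lower. HMMR lost its call without any 1 celastrol replicate or DMSO replicate 3 (highest adjusted p = 0.0721), and ANLN kept it only without DMSO replicate 2 (highest adjusted p = 0.117). DNA repair genes had 1 higher, ATR, and 4 lower of 25, also when adjusted over the list alone; FANCA, FANCD2 and FANCI, of the Fanconi anaemia pathway, were lower, at -0.47, -0.42 and -0.38 (camera adjusted p = 0.185, and 0.0301 without DMSO replicate 1, within a range of 0.0301 to 0.961). FANCA and FANCI lost their calls without DMSO replicate 3 (adjusted p = 0.0531 for both). Under TPM all 3 did, FANCA at 0.143, FANCD2 at 0.187 and FANCI at 0.222. With no filter on low values the calls of HIST1H3B, HMMR, ANLN and FANCA were lost (adjusted p = 0.0871, 0.0760, 0.115 and 0.0611), and that of ANLN also under quantile normalization (0.0633). The cell cycle inhibitor CDKN1A rose by 0.77.

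Genes of the BCL2 family and of apoptosis were higher in 10 and lower in 2 of 23 members, or 12 and 2 when adjusted over the list alone (median 0.34; camera adjusted p = 0.00684; adjusted p = 0.344 with an estimated correlation). The higher members act on both sides of cell death: MCL1, which blocks it, went from 79.6 ± 3.41 to 119 ± 3.97 FPKM, and BCL2L11, BAX and BOK, which promote it, rose by 0.58, 0.75 and 0.67, whereas BBC3, the BH3-only protein PUMA, was 2.88-fold lower. Among the left-out libraries BOK kept its call only without DMSO replicate 1 (highest adjusted p = 0.142), and it lost it with no filter on low values (0.104). BCL2 lay at 0.177 to 0.269 FPKM, with 32 to 47 reads per library, and was not tested. The camera call was lost with a minimum mean FPKM of 5 (adjusted p = 0.0664), within a range of 0.00383 to 0.344. MYC was 1.52-fold lower, at 58.2 ± 8.54 against 88.3 ± 2.50 FPKM (adjusted p = 0.00518). Of 23 tested immediate early genes, MYC among them, 11 were higher and 3 lower, or 12 and 4 when adjusted over the list alone. FOSB, FOS, PHLDA1 and SPRY4 rose by 2.06, 1.32, 1.31 and 1.05. FOSB without any 1 celastrol replicate and PHLDA1 without celastrol replicate 3 had a mean under 1 FPKM and were not tested. That list passed camera narrowly (median 0.25; adjusted p = 0.0352; adjusted p = 0.457 with an estimated correlation). It lost its call without celastrol replicate 1 (0.0602), 2 (0.0809) or 3 (0.0944) and without DMSO replicate 2 (0.0993). It also lost it with a minimum mean FPKM of 5 (0.448), under TPM (0.123), when scaled to listed reads (0.0652) and with the replicate block (0.0617), within a range of 0.000498 to 0.457.

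Of 30 listed interferon-stimulated genes only 10 reached the minimum mean of 1 FPKM. These were higher in 5 and lower in none, also when adjusted over the list alone, with IFI6, ISG15, IFI35 and BST2 higher by 1.47, 1.09, 0.81 and 0.47 (median 0.38; camera adjusted p = 0.00755; adjusted p = 0.459 with an estimated correlation). Their call was lost with no filter on low values (adjusted p = 0.257), within a range of 0.00167 to 0.459. Antigen presentation genes, of which 8 of 23 were tested, were higher in 4 of 8 and lower in none, also when adjusted over the list alone (median 0.35; camera adjusted p = 0.0110; adjusted p = 0.396 with an estimated correlation); PSMB10, a subunit of the immunoproteasome, rose by 0.78, B2M by 0.47, TAP1 by 0.44 and TAPBP by 0.27. B2M lost its call without celastrol replicate 2 or DMSO replicate 1 or 3 (highest adjusted p = 0.0794), and TAP1 and TAPBP kept theirs only without DMSO replicate 1 (highest adjusted p = 0.131 and 0.0963). With no filter on low values B2M, TAP1 and TAPBP lost their calls (adjusted p = 0.0893, 0.105 and 0.0650). NF-kappaB and inflammatory genes, of which 13 of 27 were tested, missed the threshold, with 1 higher and 3 lower of 13, or 1 and 4 when adjusted over the list alone (camera adjusted p = 0.165). IER3 rose by 1.67, NFKBIA was at -0.14 (adjusted p = 0.277) and ICAM1 at -0.02 (adjusted p = 0.831). NFKBIA turned above 0 under TPM, and ICAM1 under TPM, when scaled to listed or to nuclear reads, and without DMSO replicate 1 (0.03). Under TPM ICAM1 passed as higher (adjusted p = 0.0332).

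Cytosolic ribosomal proteins were lower in 17 of 53 members and higher in none, also when adjusted over the list alone. RPS2 fell from 1368 ± 94.6 to 728 ± 43.1 FPKM, RPL12 from 371 ± 15.5 to 202 ± 7.81, and RPL3 and RPL10A were 1.53-fold and 1.51-fold lower; their many pseudogenes can share reads. The list's median was -0.16 (camera adjusted p = 2.73e-06; adjusted p = 0.480 with an estimated correlation), and it turned to 0.08 under TPM and to 0.03 under quantile normalization, which ended the call (adjusted p = 0.887). Ribosome biogenesis genes went both ways, with 5 higher and 6 lower of 33, also when adjusted over the list alone (camera adjusted p = 0.442), and nucleophosmin, NPM1, NOP14 and FBL were 1.70-fold, 1.42-fold and 1.37-fold lower. UTP20 rose by 0.39, a call lost without celastrol replicate 1 or 2 or DMSO replicate 3 (highest adjusted p = 0.0757) and with no filter on low values (0.0622). FBL lost its call under TPM (0.0645). Chromatin modifiers were lower in 8 of 24 and higher in none, or 10 and none when adjusted over the list alone, with IDH1, a metabolic enzyme on that list, 1.73-fold lower and TET3, HDAC6 and SETDB1 lower at -0.58, -0.57 and -0.50 (median -0.20, and 0.04 under TPM; camera adjusted p = 0.00112; adjusted p = 0.396 with an estimated correlation). Splicing factors were lower in 5 and higher in 1 of 24, also when adjusted over the list alone, with HNRNPA1, SRSF6 and SF3A1 1.52-fold, 1.44-fold and 1.29-fold lower and SON higher by 0.29 (median -0.15; camera adjusted p = 0.0166; adjusted p = 0.318 with an estimated correlation). Under TPM the splicing median was 0.09 and the call was lost (adjusted p = 0.409), as when scaled to listed reads (0.0743), within a range of 0.00231 to 0.409, and SF3A1 lost its call as well (0.180). SON lost its call without celastrol replicate 1 or 2 or DMSO replicate 3 (highest adjusted p = 0.0939). Cytoskeleton and adhesion genes missed the threshold, with 3 higher and 5 lower of 22, or 5 and 5 when adjusted over the list alone (camera adjusted p = 0.830); FLNA rose by 0.73, and ITGA4, SELPLG and ACTG1 were lower, at -0.90, -0.51 and -0.50. SELPLG lost its call without DMSO replicate 3 (adjusted p = 0.0502) and under TPM (0.0622), and ITGA4 without celastrol replicate 2 or 3 or DMSO replicate 2 or 3 (highest adjusted p = 0.0700) and with no filter on low values (0.0538).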

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

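Scaling to listed reads, scaling to nuclear reads and the removal of GC and length trends were chosen after seeing the data. Under TPM there were 5266 higher and 813 lower genes, 436 at least 2-fold higher and 172 at least 2-fold lower, and scaled to listed reads there were 3024 higher. These scalings raise the median log2 fold change by 0.24 and 0.10. With a pseudocount of 1, 103 genes were at least 2-fold higher and 155 lower, since it shrinks low genes. With a mean FPKM of at least 5 these were 60 and 124 of 7571 genes tested, and with protein-coding genes alone 143 of 10072 were at least 2-fold lower. The main setting had 184 higher and 269 lower of 12685. These counts fell more steeply than the number of genes tested, so the genes left out held a larger share of such calls. The other counts of genes stayed within 1.5 times; limma-voom called 2373 higher and 2100 lower. With an estimated correlation camera called 0 lists higher and 0 lower (at an unadjusted p under 0.05, 1 and 4). Without each library in turn, higher genes ranged from 1119 to 1948 and lower genes from 1003 to 1766, with no called gene changing sign; 1020 of the higher and 871 of the lower calls were lost at least once. Fewer libraries enter these fits. Of 148 named genes that were called, 24 lost the call without at least 1 library, 22 with no filter on low values, 13 under TPM, 7 with limma without a trend and at most 3 under each other setting. HSP90AB1 turned to 0.19 under quantile normalization; the cause was not tested. Genes not called turned sign: the log2 fold change of DNAJB1 to 0.23 under TPM, 0.083 with listed reads and 0.024 with nuclear reads, and from -0.089 to 0.049 over the left-out libraries; NFKBIA to 0.10 under TPM; GAPDH to 0.18 under TPM, 0.15 under quantile normalization and 0.033 with listed reads; the log2 fold change of ICAM1 to 0.22 under TPM, 0.073 with listed reads and 0.014 with nuclear reads, and from -0.070 to 0.031 over the left-out libraries. Of these, DNAJB1, GAPDH and ICAM1 passed as higher under TPM (limma-trend adjusted p = 0.0383, 0.0330 and 0.0332). The replicate numbers share no deviation between treatments (correlations of -0.02, -0.03 and 0.03 for numbers 1 to 3, where celastrol replicates 1 and 2 correlated better with another number), so they do not pair the libraries. With the replicate block there were 1776 higher and 1617 lower genes, 188 and 276 at least 2-fold, and 10 lists higher and 8 lower; the calls of the immediate early list and TAP1 were missed. Genes under 1 FPKM were tested only without the filter, so changes in rare transcripts are mostly not covered.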

Other observations

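The test of a common yield of mitochondrial transcripts and the division of the scaling test into 2 were chosen after the result was seen, as were the genes named in this part and the reading of 1 bound noted below. Mitochondrial transcripts outside the 13 mRNAs moved unequally. The 16S rRNA, MT-RNR2, was 5.94-fold lower with celastrol (log2 fold change -2.58, SE 0.13), while the 12S rRNA, MT-RNR1, was 1.74-fold lower. Of 21 tested mitochondrial tRNAs 10 were lower and 2 were higher, MT-TG by 1.44 and MT-TR by 0.71, and the call of MT-TR was lost without at least 1 library (highest adjusted p = 0.132). So were those of MT-TV and MT-TL2, which were lower (highest adjusted p = 0.0844 and 0.0561). MT-TV, MT-TT, MT-TL2, MT-TM and MT-TW, all lower, had at most 42 reads in a library. Among long non-coding genes and pseudogenes more were lower than higher as deposited: 205 lower and 119 higher of 1277 long non-coding genes, and 152 lower and 46 higher of 857 pseudogenes, against 1393 lower and 1759 higher of 10072 protein-coding genes. The median log2 fold changes of these classes were -0.09, -0.16 and 0.04, less than the 0.24 by which TPM moves the median of all genes. The difference between the classes was not tested, and smaller classes such as snoRNA (3 higher, 2 lower of 69) went otherwise.

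The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3744 genes past the threshold and 453 of at least 2-fold, and it was the only 1 of the 10 to reach these counts; the highest of the other splits was 0 for both (limma-trend; at an unadjusted p under 0.05, 342 genes and 65 of at least 2-fold). For gene lists the real split gave 19 past camera and the highest other gave 15, again with 1 of 10 splits as high, so camera with a preset correlation also called many lists in splits that mixed the treatments. The mixed splits are uneven and keep part of the treatment difference, so their list calls need not be false. That difference also widens the spread within mixed groups, so few genes could pass there. These splits therefore do not measure what would be called without a treatment effect.

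Mitochondrially encoded mRNAs were lower with celastrol in all 13 members as deposited. Reads moved to nuclear copies were argued against, because reads on 394 annotated copies changed by -275 RPM, from 366 to 90.8. A single lower yield for the whole class had a Cochran's Q of 352 on 12 degrees of freedom against it, with the transcripts taken as independent. MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4, so reads can be exchanged within these pairs, and Q can partly measure that. Outside these pairs log2 fold changes still ran from -2.54 for MT-CO2 (SE 0.13) to -1.03 for MT-ND5 (SE 0.11). This argues against a common factor for those genes, although a yield that differs between transcripts was not tested. One scaling factor per library was argued against, since over 5 such scalings the median nearest to 0 was -1.47 with 13 of 13 lower, past the bound of -1. Under quantile normalization, which depends on abundance, 11 of 13 were lower but the median of -0.864 missed that bound. Quantile normalization gives every library the same distribution, so it would also shrink a real fall in very abundant transcripts. It therefore cannot decide whether any of the size comes from such a scaling. Lower synthesis or stability of mitochondrial RNA with celastrol is a hypothesis that was not tested.

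Genes of ATF4 and the integrated stress response were lower with celastrol. A bias from GC content or gene length was argued against, as the median moved from -1.26 to -1.21 once both trends were removed. A single deciding library was argued against too, as the median nearest to 0 without each library in turn was -1.22. It may be that the DMSO cultures had the more active response at 48 h, for instance from nutrient use in a denser culture, rather than that celastrol repressed it; no cell density and no untreated sample was analysed here, so this was not tested.

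Of 20 erythroid genes 18 were at 1 FPKM or more in all 6 libraries and 10 at 10 FPKM or more (RHAG at 247 to 296 and GATA1 at 99.7 to 161 FPKM). By contrast 9 of 20 monocytic and pan-leukocyte genes lay under 1 FPKM in all 6, among them CD14, CSF1R, CD74 and HLA-DRA. The values of all of these 9 but IRF8, and of many erythroid genes, had been seen before the lists were drawn up. The counts are therefore not independent of the pattern. MTAP, CDKN2A, CDKN2B and DMRTA1, neighbours on chromosome 9, had 0 reads in every library, where 3 reads would be at most 0.0549 FPKM. A minority of erythroid cells in a monocytic culture cannot be told apart by the listed genes, since 7 of 20 were at 10 FPKM or more. A line of erythroid type under this label cannot be told apart either. Exactly 10 of 20 were at 1 FPKM or more, which met the bound against it with no margin and was read as undecided once seen. Both bounds were set before these counts, but after low values of CD4, HLA-DRA, CD74, CSF1R, CD14, MPO, FLT3 and HOXA9 had been seen. These genes lower both counts. Of the genes not seen before, all but LST1 and IRF8 were at 1 FPKM or more in all 6 libraries. The 10 hold genes of myeloid cells (LYZ, SPI1) beside genes shared by many blood cells (LAPTM5, CD53). No reference profile of SKM-1 was analysed here, so erythroid expression of SKM-1 itself remains possible and untested.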
